A study of Homo sapiens with 5 samples.

How the data were processed

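The series holds 5 droplet single-cell RNA libraries, each from dissociated embryoids grown from H9, an established human embryonic stem cell line. Of these libraries, 3 came from embryoids at day 2, day 5 and day 8, and 2 from embryoids under endoderm-promoting conditions at day 3 and day 14. Each group is 1 library, so no group has a replicate. The deposited files hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, for 36601 genes. Only barcodes already called as cells were deposited, 38834 in all, so the RNA of empty droplets could not be measured.

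The labels name the Single Cell 3' v2 kit of 10x Genomics and 1 library per flow cell. The submitters' processing notes name Cell Ranger 3.1.0, Seurat and the genome build GRCh38. Per the file headers, the matrices were made by Cell Ranger 7.0.0 for embryoid day 2 and day 5, 7.0.1 for embryoid day 8 and endoderm day 3, and 7.2.0 for endoderm day 14. The deposited barcodes included sequences that open like the later v3 barcode list and 0 that open like the v2 list, so the kit version stays uncertain. Whether reads in introns were counted is not stated. Library, day, condition and software version cannot be separated in this design. Gene positions came from GENCODE release 29, which held 34616 of the 36601 gene identifiers and may not be the annotation the authors used.

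Cells were kept with at least 1000 detected genes and at most 20% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5, and the cells with the highest scores were removed in each library, at 0.8% per 1000 cells. Scrublet's own threshold marked at least 0.5% of cells in only 2 of the 5 libraries, so it was kept as an alternative. After these steps 34301 cells remained. Before filtering, 334, 216, 220, 261 and 920 barcodes of embryoid day 2, day 5 and day 8 and endoderm day 3 and day 14 fell under the gene minimum. Barcodes above the mitochondrial maximum numbered 246, 111, 92, 267 and 205 in the same order, and removed doublets 236, 352, 559, 647 and 401.

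For each comparison, UMIs were summed over the kept cells of a library and divided by the library's total, giving CPM (1000 times the UMIs per 1000 UMIs of the library). A gene was compared when it reached 50 CPM in either library, and was called higher or lower at a ratio of at least 4-fold. For endoderm day 3 a gene had to lie outside both embryoid day 2 and embryoid day 5 on the same side, and the ratio to the nearer library was used. There a gene was compared when it reached 50 CPM at endoderm day 3 or in both embryoid libraries. With 1 library per group no test was run and no p-value is given. Ratios carry exact Clopper-Pearson intervals and levels exact Poisson intervals at 95%, which cover counting error only and not the variation between cultures. A count of 0 was set to 3 UMIs per library, and the ratio is then given as a bound.

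Genes were named by a size rule: the 10 highest and 10 lowest ratios per comparison, plus up to 4 members with the largest ratios from each described gene list. Mitochondrial, ribosomal protein, sex-linked control and clone-named transcripts were left out of that naming. The 23 gene lists and the markers of 26 cell classes were fixed before the data were examined, as were the comparisons, the size rule and 18 kinds of alternative setting. Which lists are described, 3 added alternatives and the comparisons within clusters were chosen after the values were seen. List members needed 10 CPM in either library and counted as higher or lower at 2-fold. A list's median log2 ratio needed at least 3 measured members, with members at 0 set to their bound. Its percentile is its place among 10000 random lists of the same size drawn from 20 expression bins.

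All kept cells were clustered together in scanpy with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9), on values scaled to 10000 UMIs per cell. Libraries were not integrated, since library and condition are the same here. A cluster took the name of the class with the highest mean marker fold over the average of the other clusters, with a pseudocount of 1 CPM. At least 3 of that class's markers had to reach 10 CPM and 2-fold, and at least 1 had to be among the cluster's 10 leading genes of at least 50 CPM. No other class could hold more of these 10. This naming rule was settled after the clusters were seen and revised 1 time. It named 18 of 26 clusters, in 14 classes, and left 8 unnamed. Cells of unnamed clusters made up 4.73% of embryoid day 2, 39.5% of embryoid day 5, 87.4% of embryoid day 8, 49.2% of endoderm day 3 and 0.165% of endoderm day 14. Classes are called "-like", and a cluster that comes mostly from 1 library may mark that library as much as a cell type.

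The share of cells with a UMI of a gene was taken after thinning each cell to 3000 UMIs, since depth differed between libraries. Thinning left out 69, 119, 109, 68 and 263 shallower cells, in the order given above. The calling rule was tested on simulated data with known changes: 50 of 50 genes changed 6-fold or 12-fold were called in every comparison, and 0 of 50 at 2-fold or 3-fold. In the same simulation 0 unchanged genes were called, and 200 unchanged lists had median percentiles from 47.1 to 53.0. Both simulated libraries came from the same profile with counting noise only, so at these depths the calls were nearly fixed in advance. They say nothing about variation between cultures. Simulated clusters were named as simulated in 26 of 26 cases, and 5 of 5 without raised markers were left unnamed. Each simulated class had all of its markers raised strongly over an averaged profile, with counting noise only. Real clusters were less clear, with 8 of 26 left unnamed, so this result checks the working of the rule and not the names given. Intervals in the gene simulation covered the true ratio in 88 to 100% of the changed genes. Alternatives changed the cell filter, doublet removal, scaling, low-count minimum, clustering and thinning 1 at a time, except that the setting with all deposited barcodes left out both the filter and doublet removal. Scaling by the trimmed mean of M values (TMM) used edgeR 4.0.16 in R 4.3.3. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.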

Results

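RNA was counted in single cells of H9 human embryonic stem cell embryoids, cultures that the series title places around the time of gastrulation. Embryoids were sampled at day 2, day 5 and day 8, and embryoids under endoderm-promoting conditions at day 3 and day 14, with 1 library in each of the 5 groups. Kept cells numbered 5199 at embryoid day 2, 6278 at embryoid day 5, 7801 at embryoid day 8, 8348 at endoderm day 3 and 6675 at endoderm day 14. They held 242187466, 167958016, 131575479, 160066355 and 82102828 UMIs in the same order. Median UMIs per cell were 42723, 24537.5, 15450, 17381 and 8717, and median detected genes 7401, 5762, 4563, 4944.5 and 2920. Mitochondrial RNA made up a median of 3.25%, 2.78%, 2.44%, 4.32% and 0.965% of a cell's UMIs. No group had replicates, so each difference is between 2 libraries, and the intervals in parentheses cover counting error only.

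Embryoid day 2 consisted mostly of pluripotent epiblast-like cells, and embryoid day 5 held nascent mesoderm-like, lateral plate-like and endoderm-like cells. Pluripotent epiblast-like cells were 72.0% of day 2 (70.8 to 73.3) and 0.127% of day 5 (0.0550 to 0.251). Unnamed clusters nearest to that class held further cells. Cluster 8 held 12.7% of day 5 and 1.56% of day 8. Cluster 11, where 12 of 12 markers of the class were raised, held 3.55% of day 5, 11.1% of day 8 and 6.55% of endoderm day 3. Nascent and presomitic mesoderm-like cells were 28.0% of embryoid day 5 (26.9 to 29.1), against 0.0769% of day 2 and 4.03% of day 8 (3.60 to 4.49). Definitive endoderm-like cells made up 9.48% of embryoid day 5 (8.76 to 10.2), 4.53% of day 8 (4.07 to 5.01) and 11.2% of endoderm day 3 (10.5 to 11.9). Endoderm day 14 held smooth muscle and pericyte-like (32.1%, 31.0 to 33.3), erythroid-like (20.6%, 19.6 to 21.6), megakaryocyte-like (17.0%, 16.1 to 17.9) and hepatic and yolk sac endoderm-like cells (12.9%, 12.1 to 13.8). Several of these shares depended on the clustering. Definitive endoderm-like cells were 0% at embryoid day 5 and endoderm day 3 with each library clustered on its own, and 0% in all 3 of these libraries with a stricter cell filter. Their share was lower at endoderm day 3 than at embryoid day 5 under 4 of the 8 other settings, such as 6.29% and 8.57% with 4000 variable genes. Pluripotent epiblast-like cells ranged from 0% to 90.8% of embryoid day 2 over the settings tried, and nascent and presomitic mesoderm-like cells from 0.897% to 12.4% of day 8. Smooth muscle and pericyte-like cells were 0% of endoderm day 14 at Leiden resolution 2 and with each library clustered on its own, and hepatic and yolk sac endoderm-like cells were 5.83% in the latter setting.

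**Figure D1:**
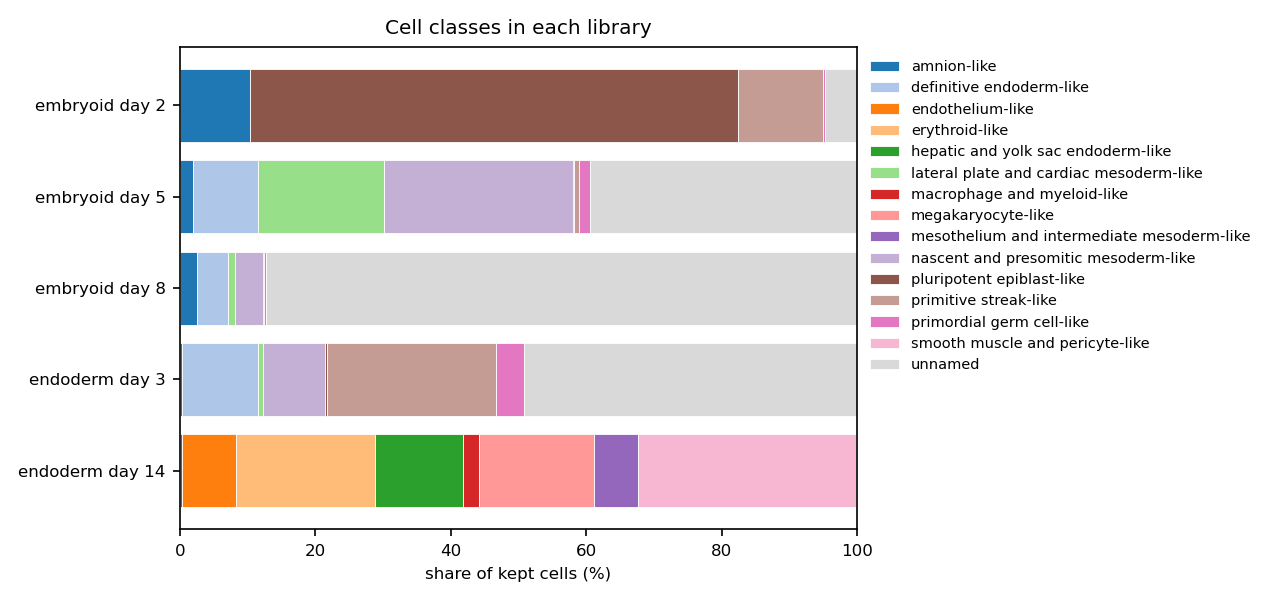
Share of kept cells (percent, horizontal axis) in each named cell class and in unnamed clusters, 1 bar per library. Pluripotent epiblast-like cells fill 72.0% of embryoid day 2, and unnamed clusters hold 87.4% of embryoid day 8.

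Single genes gave a view that did not rest on clustering. With every cell thinned to 3000 UMIs, POU5F1, a pluripotency transcription factor, was seen in 97.3% of cells at embryoid day 2 (96.9 to 97.8), 48.6% at day 5 (47.3 to 49.8) and 19.5% at day 8 (18.6 to 20.4). It was seen in 4136 of 8280 endoderm day 3 cells and in 0 of 6412 endoderm day 14 cells, which allows a share with a UMI of up to 0.0468% at this depth. Without thinning, 2 of 6675 endoderm day 14 cells had a POU5F1 UMI. MESP1, a transcription factor of early mesoderm, was seen in 77 of 5130 cells at embryoid day 2, 32.2% at day 5 and 7.37% at day 8. COL1A1, a fibrillar collagen chain, was seen in 1.48% of cells at day 2 and 62.6% at day 8. SOX17, a transcription factor of endoderm and germ cells, was seen in 12.3% of endoderm day 3 cells (11.6 to 13.0) and 7.47% of embryoid day 5 cells (6.82 to 8.15). FOXA2, another endoderm marker, did not differ in this way, at 2.73% of endoderm day 3 and 2.78% of embryoid day 5 cells. These shares depend on the thinning depth. Without thinning, at median depths of 24537.5 and 17381 UMIs, SOX17 was seen in 12.8% of embryoid day 5 and 21.1% of endoderm day 3 cells. FOXA2 was then seen in 8.51% and 7.75%, in that order.

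**Figure D2:**
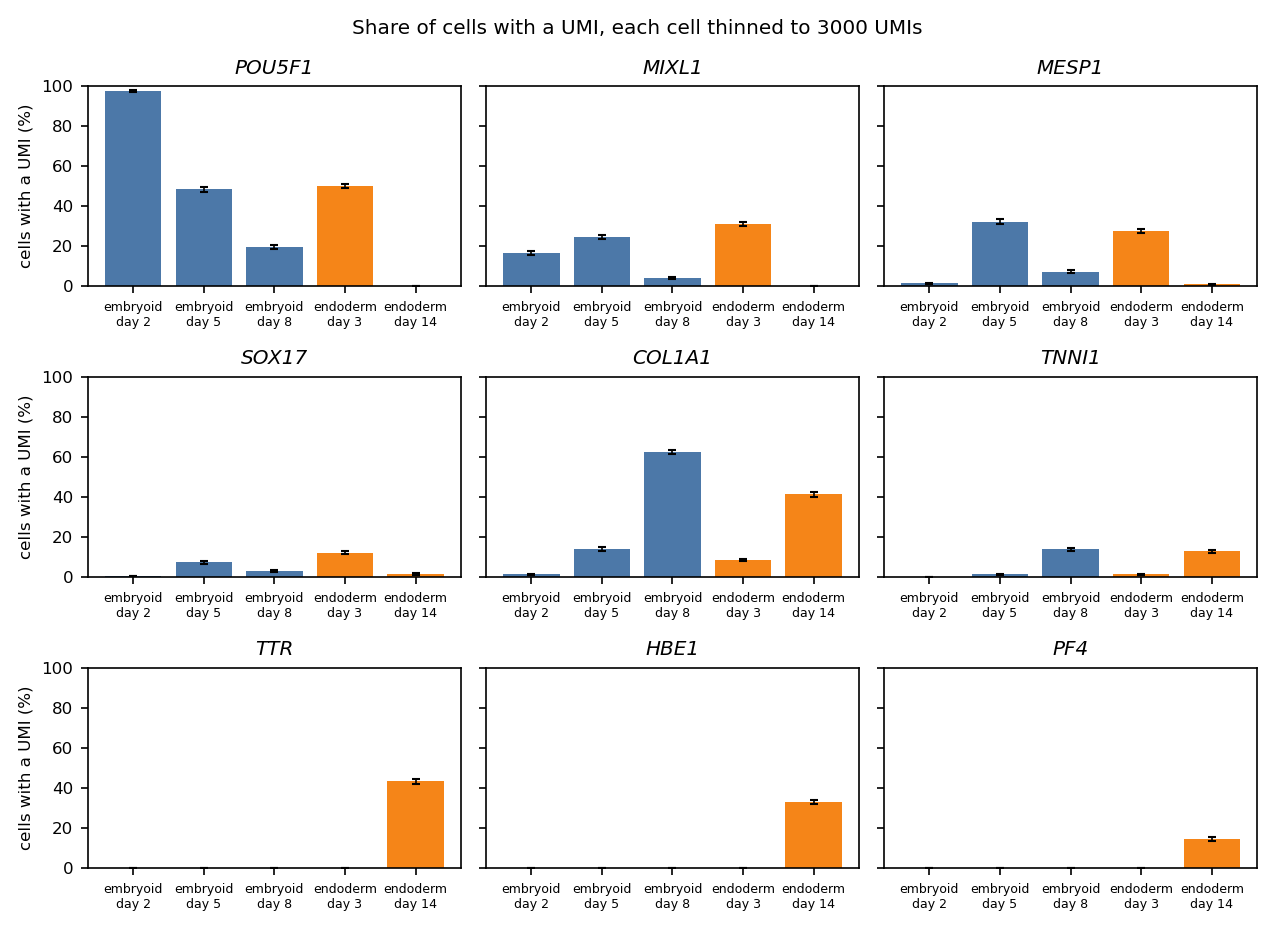
Share of cells with at least 1 UMI of each of 9 genes (percent, vertical axis) after thinning each cell to 3000 UMIs, with bars per library (blue, embryoids; orange, endoderm-promoting conditions) and 95% Clopper-Pearson intervals. POU5F1 runs from 97.3% at embryoid day 2 to 19.5% at day 8, and TTR, HBE1 and PF4 are above 1% only at endoderm day 14.

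The comparison of embryoid day 5 with day 2 asked which genes differed across the first interval of the embryoid time course. Markers of pluripotent epiblast were lower at day 5 and those of mesoderm higher. All 12 measured pluripotency markers were at least 2-fold lower, with a median log2 ratio of -1.86. SOX2, a pluripotency factor, had a log2 ratio of -3.15 (-3.20 to -3.10), USP44, a deubiquitinase of pluripotent cells, -2.60, PRDM14, a regulator of germ cells and pluripotency, -2.50, and NANOG, a homeodomain pluripotency factor, -2.21. Of 10 markers of nascent and presomitic mesoderm 8 were measured, and all 8 were higher, with a median of 5.82. These were led by LHX1 at 8.23 (8.00 to 8.47), APLNR, the apelin receptor, at 7.99 (7.76 to 8.24), MSGN1 at 6.53 and MESP2 at 5.83.

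Genes of mesenchymal cells and of body position were also higher at embryoid day 5. All 10 measured genes of the mesenchymal transition were higher (median 4.33), among them PRRX1 at 7.05, SNAI2 at 6.04, ZEB2 at 5.65 and the cadherin CDH11 at 5.33. All 9 measured markers of extraembryonic and mesenchymal stroma were higher (median 5.11), among them the collagen gene COL3A1 at 10.96 (9.84 to 12.41), FOXF1 at 9.50, PITX1 at 7.75 and LUM at 6.05. The COL3A1 ratio was 10.22 and that of LUM 5.46 with each cell weighted equally. All 6 measured posterior HOX genes, which pattern the trunk, were higher, with a median of 7.26. HOXA10 had a ratio of 10.00 (8.45 to 12.28) from 3 UMIs at day 2, HOXC8 a bound of 9.75 from 0 UMIs, HOXB8 7.37 and HOXB9 7.15. Of 13 measured genes of epithelial junctions and keratins, 9 were lower and 3 higher (median -1.63), with KRT7 at -5.07, CLDN4 at -2.24, CLDN7 at -1.94 and OCLN at -1.94. Of 9 amnion markers 5 were lower and 2 higher (median -1.61), with WNT6 at -3.22, IGFBP3 at -2.76, GABRP at -1.91 and TFAP2A at -1.90.

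Metabolic and signalling groups differed as well. Of 12 hypoxia-response genes 10 were higher and 1 lower (median 2.55), with LOX at 4.89, NDRG1 at 3.66, P4HA2 at 3.59 and ANKRD37 at 3.48. Of 17 cholesterol synthesis genes 14 were higher (median 1.19), with MVK, mevalonate kinase, at 2.16, INSIG1 at 2.00 and HMGCS1 at 1.69. Of 8 WNT response genes 4 were higher and the other 4 within 2-fold (median 1.43), with LGR5 at 7.97, LEF1 at 4.42, NKD1 at 2.42 and DKK1 at 2.40. The medians named for this comparison lay at or above percentile 99.86 of random lists, or at percentile 0 for the 3 negative ones.

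By size, RGS13, a regulator of G protein signalling (ENSG00000127074, chromosome 1, 192636138 to 192660306), led embryoid day 5. It had 0 UMIs at day 2 and 52.2 CPM at day 5, 4215-fold higher with the 0 set to 3 UMIs (interval from 3427-fold). MYL4, an embryonic and atrial myosin light chain (ENSG00000198336, chromosome 17, 47200446 to 47223679), had a log2 ratio of 10.54 (9.99 to 11.15), from 0.107 to 160 CPM. The kinase gene ZAP70 followed at 9.91, CRHBP, which encodes a binding protein of corticotropin-releasing hormone, at 9.17, the WNT-enhancing R-spondins RSPO3 at 8.90 and RSPO2 at 8.02, and TMEM88 at 8.07. Equal weight for each cell gave ZAP70 at 9.19 and RSPO3 at 8.16. Lower were CLDN10, a tight junction claudin (ENSG00000134873, chromosome 13, 95433604 to 95579759), at -4.41 (-4.49 to -4.32), the cystine transporter gene SLC7A11 at -4.04 (-4.13 to -3.95) and CHAC1, a glutathione-degrading enzyme, at -4.04. Also lower were LNCPRESS1 at -3.97, NIBAN1 at -3.92, the stress-response genes ATF5 at -3.71 and TRIB3 at -3.52, NMRK2 at -3.60, RARRES2 at -3.55 and HPGD, a prostaglandin-degrading enzyme, at -3.37. Of 3951 genes compared, 201 were at least 4-fold higher and 56 at least 4-fold lower, or 88 lower with totals that left out mitochondrial and ribosomal protein genes. In all 5 comparisons a lower minimum level gave more than 1.5 times as many such genes.

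**Figure D3:**
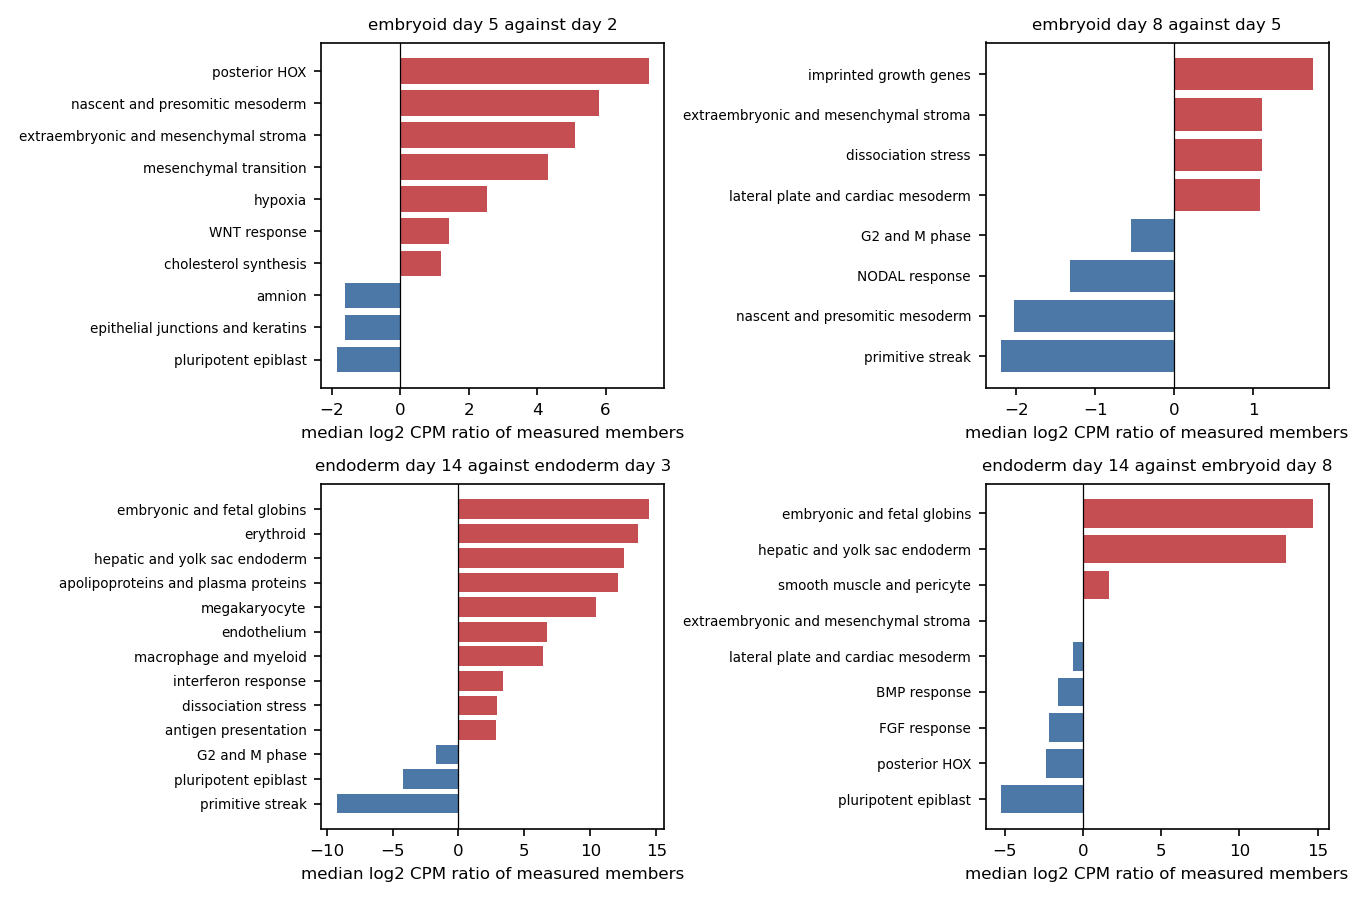
Median log2 CPM ratio (horizontal axis) of the measured members of each described gene list, with 1 panel for each of 4 comparisons and bars in red above 0 and blue below. In embryoids the nascent mesoderm list stands at 5.82 for day 5 against day 2 and at -2.03 for day 8 against day 5.

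The comparison of embryoid day 8 with day 5 covered the second interval of the time course. Most measured primitive streak and nascent mesoderm genes were lower at day 8, while the troponin gene TNNI1, the collagen genes COL3A1 and COL1A1 and the imprinted gene DLK1 were higher. Of 10 measured streak markers 9 were lower (median -2.19), with TBXT, the brachyury gene, at -3.20 (-3.36 to -3.05), MIXL1 at -3.08 and GSC, the goosecoid gene, at -2.74. Of 8 nascent mesoderm markers 7 were lower (median -2.03), with MESP1 at -3.02 (-3.06 to -2.97), MESP2 at -2.51, TBX6 at -2.15 and LHX1 at -2.11. Of 8 NODAL response genes 5 were lower and 1 higher (median -1.32), with CER1, a secreted NODAL inhibitor, at -4.09 (-4.22 to -3.95), EOMES at -2.41 and GDF3 at -1.50. The CER1 ratio was -4.74 with each cell weighted equally.

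Among 9 lateral plate and cardiac markers 5 were higher and 4 within 2-fold (median 1.09), with the troponin genes TNNI1 at 3.33 (3.23 to 3.42) and TNNT2 at 2.33, the atrial light chain MYL7 at 1.64 and TBX20 at 1.61. TNNI1 was seen in 1076 of 7692 thinned day 8 cells and in 1.45% of day 5 cells. Of 10 stroma markers 6 were higher (median 1.11), with COL3A1 at 3.05, COL1A1 at 3.00, COL6A3 at 2.29 and COL1A2 at 1.61. Of 7 imprinted growth genes 4 were higher (median 1.76), with DLK1, a Notch-pathway ligand, at 3.42, IGF2 at 2.18, MEST at 1.86 and CDKN1C, a cell cycle inhibitor, at 1.76. All 20 G2 and M phase genes were measured, 1 at least 2-fold lower and 19 within 2-fold, with a median of -0.55. HMMR was at -1.04, CDC20 at -0.93, BIRC5 at -0.79 and AURKA at -0.78. Genes known to respond to tissue dissociation were higher for 7 of 13 (median 1.11), with FOSB at 4.80 (27.8-fold, or 16.0-fold with each cell weighted equally), FOS at 2.99, ZFP36 at 2.22 and JUNB at 2.09. The negative medians lay at percentile 0 of random lists and the positive ones at percentile 100.

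The 4 lowest named ratios at embryoid day 8 belonged to metallothioneins, small metal-binding proteins encoded in a cluster on chromosome 16. MT1H (ENSG00000205358, 56669814 to 56671129) was at -6.88 (-7.09 to -6.68), MT1G at -6.35, MT1E at -6.17 and MT2A at -4.76. MT1X followed CER1 at -3.66 (-3.70 to -3.63). The family sum was 247 CPM at embryoid day 2, 1478 at day 5, 63.8 at day 8, 43.3 at endoderm day 3 and 552 at endoderm day 14. Reads of near-identical MT1 copies may have been assigned to the wrong copy, so the sum is the safer value. In definitive endoderm-like cells the sum was 659 CPM at embryoid day 5 (646 to 672), 12.8 at day 8 (9.96 to 16.1) and 15.6 at endoderm day 3 (13.7 to 17.6). Higher at day 8 by the size rule were TECRL, a gene of heart and skeletal muscle (ENSG00000205678, chromosome 4, 64275257 to 64409468), at 4.13 (4.07 to 4.20), the potassium channel partner KCNIP4 at 3.73, the smooth muscle actin ACTA2 at 2.72, the proteoglycan BGN at 2.58 and CCN1 at 2.57. Lower was SHISAL2B at -2.37. Of 3851 genes compared, 23 were at least 4-fold higher and 13 at least 4-fold lower. Lateral plate and cardiac mesoderm-like cells were 18.6% of embryoid day 5 (17.7 to 19.6) and 1.14% of day 8 (0.917 to 1.40), but this direction turned in all 8 other clustering and filter settings, where the share was higher at day 8, such as 2.82% and 49.0% at Leiden resolution 0.5 and 11.1% and 13.4% with each library clustered on its own. The largest unnamed cluster of day 8, 47.7% of its cells, was nearest to that class. It had 8 of 12 markers of the class raised and a mean log2 marker fold of 1.58, but another class held more of its leading genes. Cluster 7, which took the name and came mostly from day 5, had 4 of 12 raised and a mean of 0.387.

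**Figure D4:**
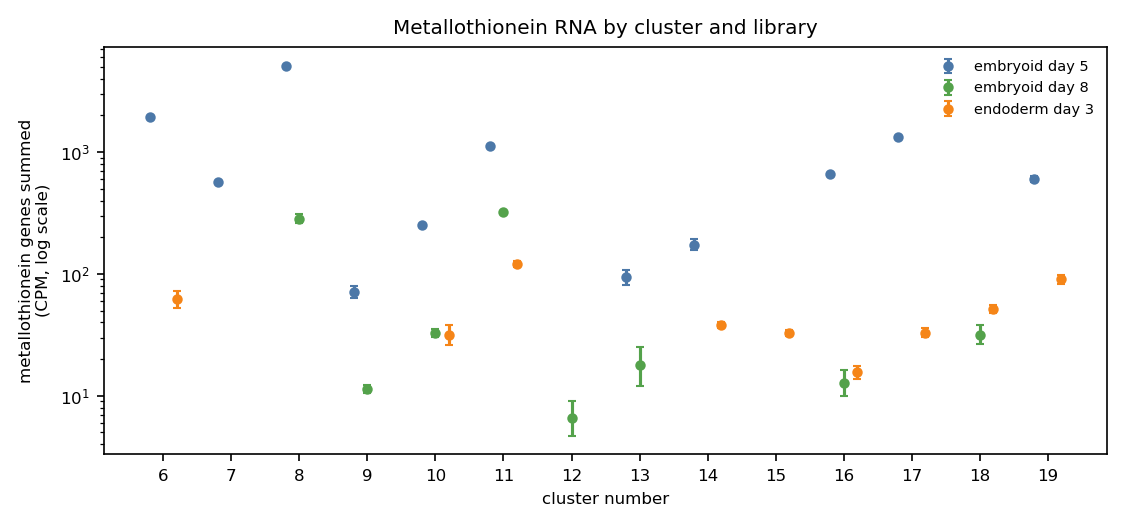
Summed CPM of 6 metallothionein genes (vertical axis, log scale) in each cluster with at least 100 cells of a library, with points for embryoid day 5 (blue), embryoid day 8 (green) and endoderm day 3 (orange) and 95% Poisson intervals. In cluster 16, the definitive endoderm-like cells, the sum is 659 CPM at embryoid day 5, 12.8 at embryoid day 8 and 15.6 at endoderm day 3.

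Endoderm day 3 was set against both embryoid day 2 and embryoid day 5, the libraries on either side in time. The series has no embryoid library of day 3. A gene that peaks between day 2 and day 5 is therefore not separated from an effect of endoderm-promoting conditions. The NODAL inhibitor gene CER1 and GSC, a gene of the embryonic organizer, were higher than in both embryoid libraries. CER1 was at 655 CPM, against 22.0 at embryoid day 2 and 62.7 at day 5, with log2 ratios of 4.90 (4.86 to 4.94) and 3.38 (3.35 to 3.41). GSC was at 46.9 CPM with ratios of 2.31 and 2.17. CER1 was seen in 32.3% of thinned endoderm day 3 cells (31.3 to 33.3), 4.76% at embryoid day 2 and 7.03% at embryoid day 5. Primitive streak-like cells were 2087 of 8348 cells at endoderm day 3, 12.6% of embryoid day 2 (11.7 to 13.6) and 0.685% of embryoid day 5. The share at embryoid day 2 was 0% under 7 of 8 other settings, and that at endoderm day 3 was up to 36.0%, with all deposited barcodes. With each library clustered on its own the direction turned, with 28.4% at embryoid day 2 and 7.03% at endoderm day 3.

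Of 9 NODAL response genes 5 were higher and 3 lower than at embryoid day 2 (median 1.56), with GDF3 at -2.80. Against embryoid day 5 the same list had 5 higher and 1 lower (median 1.06), with LEFTY1 at 2.20 and LEFTY2, both feedback inhibitors of NODAL, at 1.99. Of 10 definitive endoderm markers 6 were higher and 2 lower than at embryoid day 2 (median 3.66), with GATA6 at 6.92 (6.78 to 7.08), CXCR4 at 5.78 and FOXA2 at 4.64. Against embryoid day 5, 4 were higher and 6 within 2-fold (median 0.71), with APELA, an apelin receptor ligand, at 3.51 and PRDM1 at 1.04. APELA was also the first leading gene of cluster 11, nearest to pluripotent epiblast, which held 6.55% of endoderm day 3 and 3.55% of embryoid day 5. PRDM1 is also on the list of germ cell markers. Neither ratio is therefore particular to endoderm-like cells. Streak markers had 6 of 12 higher and 2 lower than at embryoid day 2 (median 0.88), with FGF17 at 3.51 and FGF4 at -2.45. They had 4 of 11 higher than at embryoid day 5 (median 0.69), with FGF8 at 2.67 and EOMES at 1.06.

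Some posterior HOX and hypoxia genes were lower at endoderm day 3 than at embryoid day 5. Of 6 measured posterior HOX genes 4 were lower than at embryoid day 5 (median -1.60), with HOXC8 at -6.93, HOXB9 at -2.56, HOXA10 at -1.81 and HOXB7 at -1.38. Only 2 were measured against embryoid day 2, too few for a median, HOXB8 at 6.40 and HOXB6 at 3.13. Of 12 hypoxia genes 4 were lower than at embryoid day 5 (median -0.69), with ANKRD37 at -2.04, LOX at -1.70, NDRG1 at -1.37 and BNIP3, a mitophagy receptor, at -1.10. Against embryoid day 2, 5 of 9 were higher and 1 lower (median 1.01), with P4HA2 at 2.88, EGLN3, an oxygen-sensing hydroxylase, at 2.53, BNIP3 at 2.03 and ADM at -2.18. Primordial germ cell markers were split against embryoid day 2, with SOX17 at 4.30, PRDM1 at 3.02, NANOG at -3.14 and UTF1 at -2.76 (2 of 6 higher, 2 lower, median -0.34). Against embryoid day 5, 2 of 5 were higher and 1 lower (median 0.93), with TFAP2C at 1.59, UTF1 at -1.17 and NANOG at -0.93. The positive medians of this comparison lay at or above percentile 99.64 of random lists. The negative ones lay at percentile 0 against embryoid day 5, and that of the germ cell markers against embryoid day 2 at percentile 8.38.

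By size, CER1 (ENSG00000147869, chromosome 9, 14719724 to 14722717) led the genes beyond both embryoid libraries, measured to the nearer one. It was followed by the glycophorin GYPB at 3.20 (3.15 to 3.25), PLSCR2 at 3.11, NTN1, the axon guidance cue netrin, at 3.01, SEMA3C, a semaphorin, at 2.68, GYPE at 2.41, TRMT44 at 2.34, CLSTN2 at 2.28, MYOCD, a smooth and cardiac muscle coactivator, at 2.25, and DSCAM at 2.18. GYPB and GYPE are near-identical, so their reads may be shared. Lower were MT1G at -6.59 (-6.89 to -6.30), the surface glycoprotein THY1 (ENSG00000154096, chromosome 11, 119417378 to 119424985) at -2.03 (-2.09 to -1.98), KIAA0825 at -1.83, CDCA7L at -1.71 and the noncoding RNA gene ESRG at -1.69. NRG3, NLGN1, GAL, AK4 and SFRP2 lay between -1.28 and -1.18. A higher gene needed 50 CPM only at endoderm day 3, but a lower one in both embryoid libraries, so the numbers on each side are not alike. Of 3700 genes compared, 15 were at least 4-fold higher than both and 3 lower than both, or 23 higher with totals that left out mitochondrial and ribosomal protein genes. Against embryoid day 2 alone the counts were 239 and 83 of 4124, and against embryoid day 5 alone 17 and 19 of 3829, or 26 higher with those totals.

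Endoderm day 14 against endoderm day 3 showed how cultures under endoderm-promoting conditions differed between their earlier and later sampling. Liver and yolk sac genes, globins and markers of blood and vessels were higher at day 14, and streak and pluripotency genes lower. All 14 hepatic and yolk sac endoderm markers were higher, with a median log2 ratio of 12.54. TTR, the thyroid hormone carrier transthyretin, was at 13794 CPM at day 14 against 0.0562 at day 3, a ratio of 17.90 (16.98 to 19.03). All 22 apolipoprotein and plasma protein genes were higher (median 12.08), among them APOC3 at 20.32 (17.84 to 25.63) and the antitrypsin gene SERPINA1 at 18.30 (15.82 to 23.61), both from 1 UMI at day 3. APOA4 was at 17.10, AHSG at 16.61 and the fibrinogen chain FGB at 15.18. With each cell weighted equally the median of the hepatic list was 11.69 and that of the plasma proteins 10.79, with APOC3 at 18.12, SERPINA1 at 16.98, TTR at 16.77, APOA4 at 16.09, AHSG at 15.17 and FGB at 14.40.

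All 8 embryonic and fetal globins, the oxygen carriers of red cells, were higher (median 14.42), with HBZ at 17.42 (16.61 to 18.37), HBE1 at 16.08, HBG2 at 15.25 and HBG1 at 14.92. HBZ reached 13124 CPM. The pairs HBG1 and HBG2, HBA1 and HBA2, and HBB and HBD are near-identical, and the annotated spans of HBG2 and HBE1 overlap, so how their reads were divided is uncertain. Of 11 erythroid markers 10 were higher (median 13.63). With the stricter filter of 2000 genes and 10% mitochondrial UMIs the globin median was 13.61 and the erythroid median 12.75, with HBZ at 16.49, HBE1 at 15.12, HBG2 at 14.55 and HBG1 at 14.20. Equal weight for each cell gave HBE1 at 16.82 and HBG2 at 15.83. Barcodes under the gene minimum at endoderm day 14 carried 15.2% of their UMIs in globins, against 3.18% in kept cells. The erythroid-like share was 10.9% with the stricter filter and 23.1% with neither filter nor doublet removal.

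All 8 megakaryocyte markers were higher (median 10.40), with the platelet chemokines PPBP at 15.85 (14.63 to 17.48), or 16.52 with each cell weighted equally, and PF4 at 12.70. PLEK was at 11.53, and the platelet receptor part GP9 had a bound of 12.49, or 13.11 with equal weight. With all deposited barcodes GP9 had 1 UMI at day 3, so its ratio of 14.35 there is no longer a bound. Of 11 endothelial markers 10 were higher (median 6.68), with the vascular cadherin CDH5 at 9.52, ESAM at 9.29, PLVAP at 8.71 and PECAM1 at 8.20. Of 12 macrophage and myeloid markers 7 were measured, and all 7 were higher (median 6.38). Among them were C1QC, a complement chain, at a bound of 10.34, PTPRC at 8.59, LYZ at 7.72 and CD68 at 6.38. Interferon response genes had 9 of 11 higher and 1 lower (median 3.39), with IFI6 at 9.89, MX1 at 7.91, IFIT3 at 7.56 and IFIT1 at 6.83. Antigen presentation genes had 6 of 7 higher (median 2.82), with NLRC5 at 6.16, B2M at 3.71, HLA-B at 3.12 and TAP1 at 2.82. Dissociation-response genes had 10 of 14 higher and 1 lower (median 2.92), with DUSP1 at 5.37, ZFP36 at 4.98, FOSB at 4.85 and JUNB at 4.65.

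All 11 measured streak markers were lower at endoderm day 14 (median -9.23). EOMES had 0 UMIs there, 3513-fold lower with the 0 set to 3 UMIs (interval from 2857-fold). GSC had 0 UMIs, a bound of -10.33, MIXL1 was at -10.38 and FGF8 at -10.04. Of 10 pluripotency markers 9 were lower (median -4.21), with POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) at -13.83 (-16.88 to -11.98) from 2 UMIs, L1TD1 at -8.65, SOX2 at -6.38 and TDGF1 at -5.97. POU5F1 was at -11.67 with each cell weighted equally and -14.66 with the stricter filter. Equal weight gave CYP26A1 at -14.64, and all deposited barcodes gave GSC a ratio of -12.06 from 1 UMI. CYP26A1, a retinoic acid-degrading enzyme, was at -13.62 (-18.92 to -11.14) from 1 UMI, SHISAL2B at -10.71, the microRNA host gene MIR302CHG at -10.22, LHX1 at -10.13, CER1 at -10.01, GRP at -9.76 and LGR5 at -9.54. All 20 G2 and M phase genes were measured and 19 were lower (median -1.67), with CENPE at -2.68, CENPF at -2.25, BUB1B at -2.23 and BIRC5 at -2.13. The positive medians lay at or above percentile 97.88 of random lists and the negative ones at 0. Of 4463 genes compared, 383 were at least 4-fold higher and 250 at least 4-fold lower, and the median of all was -0.25. Globin and plasma protein genes took 10.4% of the UMIs of endoderm day 14 and 0.112% of those of endoderm day 3, which lowers every other gene's CPM.

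Within endoderm day 14, genes of hepatic and blood cells also had UMIs in cells of other classes. TTR was seen in 100% of thinned hepatic and yolk sac endoderm-like cells, which had a median of 20652 UMIs before thinning, and in 31.6% to 37.1% of the cells of other classes, whose medians ran from 7484.5 to 13710.5 UMIs. HBZ was seen in 98.7% of erythroid-like cells and in 18.7% to 32.6% of the other classes. Free RNA, doublets and low expression were not separated for these shares, which are taken as the background. PF4 was seen in 70.8% of megakaryocyte-like cells (68.0 to 73.5) and 2.35% to 4.54% of the other classes, and CDH5 in 73.7% of endothelium-like cells (69.6 to 77.6) and at most 0.736% of the others. TTR, HBZ, PF4 and CDH5 are leading genes of the clusters named for these classes. Each was therefore high in its own class by selection. Megakaryocyte-like cells also held globin RNA in other proportions than erythroid-like cells did. Their ratio of HBE1 to HBZ was 1.65 (1.61 to 1.69), against 0.217 (0.216 to 0.218) in erythroid-like cells. HBD, a globin gene, stood at 1656 CPM in megakaryocyte-like and 19.3 CPM in erythroid-like cells. It is a leading gene of the megakaryocyte-like cluster, so it was high there by selection. HBE1 stood at 1681 CPM in megakaryocyte-like cells and 268 CPM in cells outside the blood classes. HBZ stood at 1019 and 1256 CPM in that order, so it may be background in megakaryocyte-like cells. The ratio of 1.65 is then not that of the cells' own RNA.

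**Figure D5:**
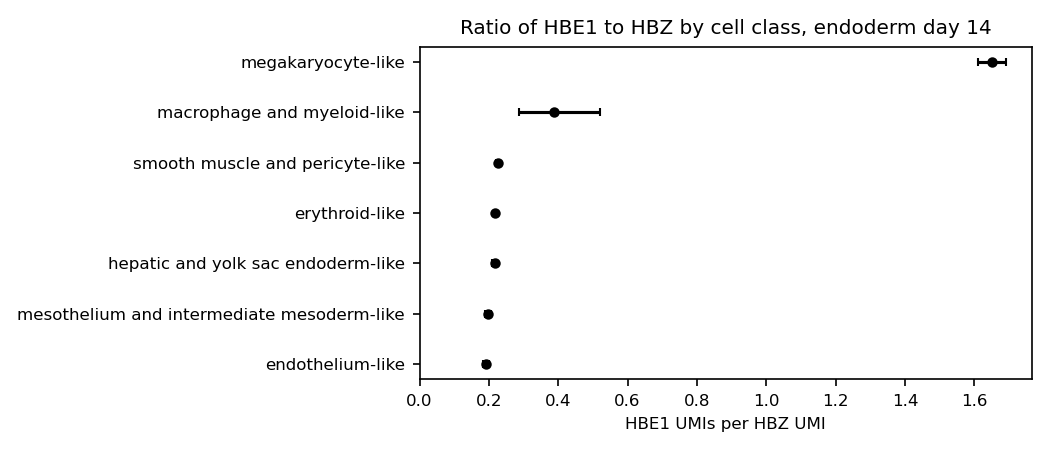
Ratio of HBE1 to HBZ UMIs (horizontal axis) in the cells of each named class at endoderm day 14, as points with 95% exact intervals. Megakaryocyte-like cells stand at 1.65 and erythroid-like cells at 0.217.

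Endoderm day 14 against embryoid day 8 set the latest library of each condition side by side, and their days differ. Globins and liver genes were higher in endoderm day 14, and posterior HOX, FGF and BMP response genes lower. All 8 globins were higher (median 14.71), with HBG1 (ENSG00000213934, chromosome 11, 5248079 to 5249859) at 18.22 (15.74 to 23.52) from 1 UMI, HBZ at 17.26, HBG2 at 16.04 and HBE1 at 15.02. With the stricter filter the globin median was 13.77, with HBG1 at 17.50, HBZ at 16.33, HBG2 at 15.34 and HBE1 at 14.05, and HBG1 was at 17.41 with each cell weighted equally. All 14 hepatic and yolk sac endoderm markers were higher (median 12.95), with the fibrinogen chain FGG at 16.98 (14.50 to 22.29) from 1 UMI, APOC3 at 16.58, TTR at 15.21 and AHSG at 14.91. SERPINA1 had 0 UMIs at embryoid day 8 and was 88548-fold higher with the 0 set to 3 UMIs (interval from 72012-fold). With each cell weighted equally the hepatic median was 11.59, with FGG at 14.75, APOC3 at 15.14, TTR at 13.81, AHSG at 13.83 and SERPINA1 at a bound of 15.11. PPBP was at 15.57, or 16.28 with that weighting.

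Of 8 posterior HOX genes 7 were lower (median -2.37), with HOXA10 at -9.44 from 2 UMIs, HOXA9 at a bound of -8.18, HOXB9 at -6.69 and HOXC6 at -2.80. Of 9 FGF response genes 8 were lower (median -2.21), with IL17RD at -3.91, ETV4 at -3.70, SPRY2 at -2.38 and SPRY4 at -2.27. Of 10 BMP response genes 8 were lower (median -1.61), with MSX2 at -4.40, MSX1 at -4.15, SMAD9 at -3.22 and BAMBI at -2.60. All 11 pluripotency markers were lower (median -5.24), with POU5F1 at -13.15 (-16.20 to -11.30) and NANOG at -8.95, each from 2 UMIs, L1TD1 at -7.70 and SOX2 at -7.52. Equal weight for each cell gave POU5F1 at -10.81, NANOG at -8.22 and HOXC6 at -3.54, and the stricter filter gave POU5F1 at -13.97.

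Mesenchymal markers were divided. Of 12 stroma markers 5 were higher and 4 lower (median 0.02), with the proteoglycan DCN at 8.09 (7.87 to 8.32) and POSTN at 6.36, and with TBX4, a limb and allantois factor, at -6.75 and BMP4 at -3.65. Of 6 smooth muscle and pericyte markers 4 were higher and 1 lower (median 1.67), with the intermediate filament DES at 3.52, TAGLN at 2.61, ACTA2 at 1.93 and RGS5 at -4.92. Of 10 lateral plate and cardiac markers 1 was higher and 3 lower (median -0.62), with the cardiac actin ACTC1 at -3.46 (-3.48 to -3.44), NKX2-5 at -2.57, MYL7 at -1.44 and TNNT2 at 1.27. The stroma median lay at percentile 81.96 of random lists, the cardiac one at 3.28, the posterior HOX one at 0.39 and the smooth muscle one at 99.95. Those of the globin and hepatic lists lay at 100 and the remaining ones at 0. Other named genes were ESRG at -12.95 (-18.25 to -10.47) from 1 UMI, PLPPR5 at -10.03, the growth factor FGF19 at -9.19, the cystatin CST1 at -9.13, MIR302CHG at -8.55, LGR5 at -7.94, PTPRZ1 at -6.50 and PCAT14 at -6.20. Equal weight gave ACTC1 at -4.05, FGF19 at -8.43, MIR302CHG at -7.95, PLPPR5 at -9.41 and TAGLN at 1.86. Of 4288 genes compared, 281 were at least 4-fold higher and 167 lower, and the median of all was -0.19.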

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

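All cells but those of cluster 5, endoderm day 14 without its erythroid-like and megakaryocyte-like cells, and totals without globin and plasma protein genes were alternatives chosen only after the results were seen. No paired analysis was possible because each group held 1 library and no test was run. Ratios and list medians between libraries were rerun under 5 settings: all deposited barcodes, the stricter filter, TMM, the mean of per-cell CPM, and totals without mitochondrial and ribosomal protein genes. None of at least 2-fold changed sign there, and ratios within clusters were rerun under no setting. The counts of genes at least 4-fold apart stayed within 1.5-fold in all 5 comparisons under TMM scaling, all deposited barcodes with neither filter nor doublet removal, the stricter filter, the mean of per-cell CPM and removal of cluster 5, and in both endoderm day 14 comparisons under the other 2 added alternatives. TMM scaling shifted the median ratio by -0.11 for embryoid day 8 against day 5 and -0.18 for endoderm day 3 against embryoid day 2. Totals without mitochondrial and ribosomal protein genes shifted it by -0.16 for endoderm day 14 against day 3 and -0.15 against embryoid day 8, and totals without globin and plasma protein genes by 0.16 in both. Of the genes called between endoderm day 3 and embryoid day 5, 47.2% were higher, against 37.1% under TMM, 41.4% with the mean of per-cell CPM and 53.1% with totals without mitochondrial and ribosomal protein genes. Depth set the shares of cells with a UMI: of 98 shares, 98 moved without thinning, 96 at 1500 UMIs and 97 at 6000 UMIs.

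Counts followed the minimum level, since a lower minimum compares more genes. At least 10 CPM gave 578 higher and 183 lower for embryoid day 5 against day 2, 72 higher and 50 lower for embryoid day 8 against day 5, 1050 higher and 668 lower for endoderm day 14 against day 3, 53 higher and 19 lower for endoderm day 3 beyond both embryoid libraries and 823 higher and 493 lower for endoderm day 14 against embryoid day 8. A minimum of 10 UMIs alone gave 2661 higher and 1012 lower for embryoid day 5 against day 2, 837 higher and 341 lower for embryoid day 8 against day 5, 3405 higher and 2599 lower for endoderm day 14 against day 3, 395 higher and 177 lower for endoderm day 3 beyond both embryoid libraries and 2711 higher and 2335 lower for endoderm day 14 against embryoid day 8. Totals without mitochondrial and ribosomal protein genes gave 88 lower for embryoid day 5 against day 2 and 23 higher for endoderm day 3 beyond both embryoid libraries, and the cause was not tested.

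Class shares moved under every clustering and cell filter. Apart from the erythroid-like cells lost to the stricter filter, described below, the cause was not tested. With 4000 variable genes, shares outside the first interval were as follows. Embryoid day 2 held 8.00% amnion-like, 90.8% pluripotent epiblast-like and 0% primitive streak-like. Embryoid day 5 held 8.57% definitive endoderm-like, 10.2% lateral plate and cardiac mesoderm-like and 22.2% nascent and presomitic mesoderm-like. Embryoid day 8 held 28.3% lateral plate and cardiac mesoderm-like and 2.10% nascent and presomitic mesoderm-like. Endoderm day 3 held 6.29% definitive endoderm-like, 0.216% lateral plate and cardiac mesoderm-like, 6.83% nascent and presomitic mesoderm-like and 34.7% primitive streak-like. Endoderm day 14 held 3.60% macrophage and myeloid-like, 15.7% megakaryocyte-like, 8.49% mesothelium and intermediate mesoderm-like and 30.3% smooth muscle and pericyte-like.

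Leiden resolution 0.5 gave these shares. At embryoid day 2 there were 89.7% pluripotent epiblast-like and 0% primitive streak-like. At embryoid day 5 there were 2.82% lateral plate and cardiac mesoderm-like and 25.9% nascent and presomitic mesoderm-like. At embryoid day 8 there were 49.0% lateral plate and cardiac mesoderm-like and 3.49% nascent and presomitic mesoderm-like. At endoderm day 3 there were 10.2% definitive endoderm-like, 0% lateral plate and cardiac mesoderm-like, 6.85% nascent and presomitic mesoderm-like and 26.5% primitive streak-like. At endoderm day 14 there were 0% macrophage and myeloid-like and 19.4% megakaryocyte-like.

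Leiden resolution 2 gave these. The cells of embryoid day 2 were 9.02% amnion-like, 56.8% pluripotent epiblast-like and 0% primitive streak-like. The cells of embryoid day 5 were 8.63% definitive endoderm-like, 19.7% lateral plate and cardiac mesoderm-like and 26.3% nascent and presomitic mesoderm-like. The cells of embryoid day 8 were 29.5% lateral plate and cardiac mesoderm-like and 0.897% nascent and presomitic mesoderm-like. The cells of endoderm day 3 were 4.96% nascent and presomitic mesoderm-like and 30.2% primitive streak-like. The cells of endoderm day 14 were 3.69% macrophage and myeloid-like, 15.7% megakaryocyte-like and 0% smooth muscle and pericyte-like.

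Each library clustered on its own gave these. For embryoid day 2 the shares were 0% amnion-like, 0% pluripotent epiblast-like and 28.4% primitive streak-like. For embryoid day 5 the shares were 0% definitive endoderm-like, 11.1% lateral plate and cardiac mesoderm-like and 20.3% nascent and presomitic mesoderm-like. For embryoid day 8 the shares were 1.28% amnion-like, 13.4% lateral plate and cardiac mesoderm-like and 12.4% nascent and presomitic mesoderm-like. For endoderm day 3 the shares were 0% definitive endoderm-like, 0% lateral plate and cardiac mesoderm-like, 7.19% nascent and presomitic mesoderm-like and 7.03% primitive streak-like. For endoderm day 14 the shares were 0.315% endothelium-like, 5.83% hepatic and yolk sac endoderm-like, 11.5% megakaryocyte-like and 0% smooth muscle and pericyte-like.

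All deposited barcodes, with no filter and no doublet removal, gave these. Embryoid day 2 had 76.2% pluripotent epiblast-like and 0% primitive streak-like. Embryoid day 5 had 30.4% nascent and presomitic mesoderm-like. Embryoid day 8 had 2.00% amnion-like, 5.08% definitive endoderm-like and 47.0% lateral plate and cardiac mesoderm-like. Endoderm day 3 had 7.25% definitive endoderm-like, 1.22% lateral plate and cardiac mesoderm-like, 6.55% nascent and presomitic mesoderm-like and 36.0% primitive streak-like. Endoderm day 14 had 23.1% erythroid-like, 15.3% hepatic and yolk sac endoderm-like, 3.54% macrophage and myeloid-like, 18.0% megakaryocyte-like, 5.57% mesothelium and intermediate mesoderm-like and 26.6% smooth muscle and pericyte-like.

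Doublets kept gave these. Shares at embryoid day 2 were 84.4% pluripotent epiblast-like and 0% primitive streak-like. Shares at embryoid day 5 were 8.30% definitive endoderm-like, 23.1% lateral plate and cardiac mesoderm-like and 26.8% nascent and presomitic mesoderm-like. Shares at embryoid day 8 were 45.4% lateral plate and cardiac mesoderm-like and 5.73% nascent and presomitic mesoderm-like. Shares at endoderm day 3 were 5.73% definitive endoderm-like, 2.58% lateral plate and cardiac mesoderm-like, 7.40% nascent and presomitic mesoderm-like and 30.3% primitive streak-like. Shares at endoderm day 14 were 14.01% hepatic and yolk sac endoderm-like, 18.0% megakaryocyte-like and 29.5% smooth muscle and pericyte-like.

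Scrublet's own threshold gave these. Cell shares for embryoid day 2 were 84.2% pluripotent epiblast-like and 0% primitive streak-like. Cell shares for embryoid day 5 were 2.22% lateral plate and cardiac mesoderm-like and 30.5% nascent and presomitic mesoderm-like. Cell shares for embryoid day 8 were 28.1% lateral plate and cardiac mesoderm-like and 2.94% nascent and presomitic mesoderm-like. Cell shares for endoderm day 3 were 6.42% definitive endoderm-like, 0.0584% lateral plate and cardiac mesoderm-like, 10.3% nascent and presomitic mesoderm-like and 30.9% primitive streak-like. Cell shares for endoderm day 14 were 14.3% hepatic and yolk sac endoderm-like and 29.2% smooth muscle and pericyte-like.

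The stricter filter of 2000 genes and 10% mitochondrial UMIs gave these. In embryoid day 2, 9.44% amnion-like, 57.4% pluripotent epiblast-like and 0% primitive streak-like were found. In embryoid day 5, 0% definitive endoderm-like, 14.6% lateral plate and cardiac mesoderm-like, 25.7% nascent and presomitic mesoderm-like and 2.54% primordial germ cell-like were found. In embryoid day 8, 0% definitive endoderm-like and 23.7% lateral plate and cardiac mesoderm-like were found. In endoderm day 3, 0% definitive endoderm-like, 0.402% lateral plate and cardiac mesoderm-like, 11.9% nascent and presomitic mesoderm-like, 30.4% primitive streak-like and 9.93% primordial germ cell-like were found. In endoderm day 14, 8.91% endothelium-like, 10.9% erythroid-like, 14.2% hepatic and yolk sac endoderm-like, 2.78% macrophage and myeloid-like, 8.49% mesothelium and intermediate mesoderm-like and 38.0% smooth muscle and pericyte-like were found. Erythroid-like cells had a median of 1770.5 detected genes in the main setting, so a minimum of 2000 genes removed most of them. This filter kept 4960 of the 6675 endoderm day 14 cells.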

Other observations

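All tests of explanations given here were chosen only after the results they concern were seen. Genes of collagen, body position and metabolism added to the picture of embryoid day 5 against day 2. All 4 measured anterior HOX genes were higher (median log2 ratio 5.57), with HOXB3 at 6.48, HOXB4 at 6.48, HOXB5 at 4.67 and HOXB2 at 2.59. Of 18 collagen and matrix genes 17 were higher (median 2.80), with COL5A1 at 5.89 and COL5A2, which form a fibrillar collagen, at 5.78. Of 18 glycolysis genes 7 were higher and 11 within 2-fold (median 0.90), with LDHA, lactate dehydrogenase, at 2.04, PFKP at 1.94 and PKM at 1.91. Of 6 retinoic acid pathway genes 5 were higher and 1 lower, with CRABP2 at 2.73, STRA6, the retinol transporter, at 2.56 and CRABP1 at -1.77. At endoderm day 14 against day 3, all 8 WNT response genes were lower (median -2.53), with LGR5 at -9.54, SP5 at -7.33 and NKD1 at -5.21. There, 5 of 7 imprinted growth genes were higher (median 2.86), with DLK1 at 8.29, IGF2 at 4.19 and CDKN1C at 3.81. All 6 hematopoietic progenitor markers were higher (median 6.85), with TAL1, a blood and endothelial factor, at 11.52 (9.66 to 14.56) from 2 UMIs and GATA1 at 8.67.

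Cells of the same cluster differed between libraries in comparisons chosen after the data were seen. Among definitive endoderm-like cells, 933 of endoderm day 3 and 595 of embryoid day 5, CER1 was at 886 and 139 CPM, a log2 ratio of 2.67 (2.60 to 2.74), and LEFTY1 had a ratio of 2.67 (2.47 to 2.88). APOA1, the main protein of high-density lipoprotein, was lower at endoderm day 3, at -3.16 (-3.23 to -3.08), and ACTC1 at -3.38 (-3.53 to -3.24). Of the same cluster, 353 embryoid day 8 cells against those of embryoid day 5 had CER1 at -6.58, MESP1 at -3.84, POU5F1 at -2.13 and FOS at 2.83. The whole libraries had CER1 at -4.09, MESP1 at -3.02 and FOS at 2.99. Free RNA of each library was not separated from the cells' own RNA in these comparisons. Among primordial germ cell-like cells, 344 of endoderm day 3 and 103 of embryoid day 5, HPGD was at 2.06 (1.89 to 2.23) and FOS at 2.25 (1.91 to 2.61). FOS is among the genes known to respond to dissociation, of which 4 of 13 were higher in this comparison (median 0.71) and 5 of 13 in that of embryoid day 8 with day 5 (median 0.89), so handling is not separated from cell state.

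Metallothionein RNA was higher at embryoid day 5 than at embryoid day 8, by a log2 ratio of the family sum of -4.54 for day 8 over day 5. Since this sum does not depend on which of the summed copies took a read, reads moved among them could not give the difference. Reads lost to copies outside the sum, or left unassigned, were not measured. Cluster sizes alone, over all clusters with day 5 cells, would have given -1.90, short of the -2.27 set as the limit. Of day 8 UMIs, 91.3% lay in clusters with at least 100 day 5 cells. Free RNA from cluster 8, which these genes led at 5096 CPM, would even out the other clusters. These instead differed 27.3-fold within day 5, from 70.7 to 1931 CPM. These tests argue against cell makeup, free RNA from cluster 8 and reads moved among the summed copies as the whole cause. Metal or other factors of the medium, the handling of a culture and the library itself were not tested and stay open, since each day is 1 library.

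HBE1 RNA in megakaryocyte-like cells of endoderm day 14 could come from free RNA or from doublets with erythroid-like cells. Their ratio of HBE1 to HBZ was 7.73 times (7.36 to 8.11) that of cells outside the blood classes, and 7.60 times (7.35 to 7.86) the higher of the ratios of those cells and of erythroid-like cells. A mixture of these sources would lie between them, so both tests argue against such doublets, or RNA with these ratios, as the source of most HBE1 there. The references had near-equal ratios, 0.214 and 0.217. Cells outside the blood classes only stood in for free RNA, which was not measured. Macrophage-like cells, with less HBZ (74.7 CPM), had a ratio of 0.388 (0.286 to 0.521), also below the 1.65 of megakaryocyte-like cells. A megakaryocyte or shared progenitor program with its own globin makeup stays a hypothesis, as no biological explanation was tested. Reads divided between HBE1 and the overlapping span of HBG2 also stay open.

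Cluster 5, with 226 cells of embryoid day 2 and 89 of embryoid day 8, had mitochondrial shares of 0.167% and 0.240%, against 3.43% and 2.63% in the other cells. Nuclei stripped of cytoplasm might explain this, but MALAT1, a nuclear RNA, was 0.438 times the level of other cells at embryoid day 2, which argues against it there, and 1.66 times at day 8, where NEAT1, another nuclear RNA, at 4.13 times (0.115 at day 2) and ribosomal protein genes at 30.6% of UMIs against 22.8% left it undecided. The mitochondrial share was at most 0.0910 times that of the other cells in either library, but that is the pattern itself and cannot exclude droplets filled by free RNA, which could not be measured. At embryoid day 8 the stress genes GDF15 and DDIT3 stood at 33.6 and 33.8 times the other cells, and at day 2 at 0.433 and 1.60 times. Both are among the leading genes of cluster 5, so they were high there by selection, and free RNA stays open in both libraries. No biological explanation was tested.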
